A study of Mus musculus with 12 samples.

How the data were processed

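Split-DamID was used on genomic DNA from the external genitalia of male mouse embryos. In this assay the DAM methyltransferase is divided into inactive parts, here fused to the androgen receptor (AR) and to the coactivator p300, and adenine in GATC is methylated where the parts meet. Per the labels' protocols, methylated GATC was cut with DpnI, adapters were ligated to the cut ends, and the fragments were amplified over 6 and then 25 cycles of PCR before sequencing. The labels describe 12 samples, 7 with the split-DAM and Msx2-rtTA alleles (SpDAM+; Msx2Rtta+) and 5 without them (SpDAM-; Msx2Rtta-).

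Per the submitters' processing notes, BWA, SAMtools and HOMER were used with the mm10 genome, and no versions or settings were stated. The deposited data are 7 peak lists annotated with HOMER against mm10, per the file headers. Headers of lists 1 to 3 name 1 library code against 3 further codes, and headers of lists 4 to 7 name a single code. These codes do not appear in the labels, so no list could be tied to a sample or a group. The contrast of SpDAM+ with SpDAM- samples was therefore not computed, and the planned sign-flip tests over lists as replicates were replaced by tests within each list, with counts of lists.

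The deposited peak score is a caller's value scaled within its list, per the file headers and the values. All scores checked in a list, up to 80 multiples of its lowest step, were whole multiples of that step within 0.1 score units, so the score divided by the step was taken as the number of reads in the peak. If the scale is HOMER's default, the step also gives the depth of the library, but the sources do not state the scale. The focus ratio is a fraction between 0 and 1 deposited by the authors, and was summarised by its median per list. Distances to the nearest transcription start site (TSS), gene names and annotations were used as deposited. Coordinates are mm10.

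Peaks of all lists were merged where they overlapped by at least 1 bp, and a merged position in at least 4 of the 7 lists was called recurrent. Chance was set by permuting positions, in 100 draws in which every peak was placed anywhere on its chromosome, and by 100 draws in which it was moved by 20 to 200 kb. The smallest p the draws can give is 0.0099 one-sided and 0.0198 two-sided. Within each list, recurrent peaks were compared with peaks found in no other list by Fisher's exact test for the promoter share and by a permutation test with 100000 resamples for the median number of reads. Both were two-sided and adjusted over the 7 lists by the method of Benjamini and Hochberg. Shares of peaks on chromosome X have Wilson 95% intervals. Reads made by PCR without molecular identifiers are not independent molecules, so these intervals cover counting error only.

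A gene's territory is the stretch of genome in which its TSS is the nearest. TSS positions were recovered from the deposited distances, and genes that the lists never name were placed at their midpoint in the RefSeq annotation of GRCm38. Of the 18765 genes named in the lists, 18736 were in that annotation. The number of lists expected for each of 24330 genes came from its territory, the length of its chromosome and the peaks of each list there. Its upper tail was tested for independent lists with Benjamini-Hochberg adjustment. The map of TSS positions was revised after the first gene results had been seen, because that map misplaced some genes. In the revised map, a gene that the lists never name was left out where it would have been nearest to a deposited peak. With each list held out in turn, the first map returned 90.3% to 91.2% of the deposited gene names, and the revised map returned 96.1% to 96.8%. Built from all lists, the revised map returned 99.6%. Both maps rest on the deposited peaks, so observed peaks can match them better than shuffled peaks do. Results of both maps are given with the alternatives, since calls differed between them.

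Before the data were examined, 15 gene lists with 571 genes were fixed. They held canonical AR targets, genes of genital development, signalling pathways, cell type markers, nuclear receptors with coregulators, and housekeeping genes. Of the 588 entries, 573 matched the annotation. Members with a peak in at least 4 lists were counted against 10000 random gene sets, drawn for each member from the 100 genes on either side of its rank by territory, as a permutation of genes with a two-sided p adjusted over the 15 lists.

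Genes named in the text follow a rule fixed before the data were examined. It takes the 25 genes with a peak in the most lists, with ties broken by the mean over lists of the gene's best score percentile. It adds up to 4 members of each gene list with a peak in at least 4 lists, in the same order, and also Ar, Ep300 and Msx2. The list counts of the 25 genes and of these list members are therefore high by selection. Genes at recurrent positions, at the highest peaks or above their territory were named after their values were seen.

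The procedures were tested on simulated data. All planted positions in 4 to 7 lists were recovered among 96895 simulated regions, with 0 further ones in at least 4 lists. Peaks of a planted position had the same centre, which the overlap rule must recover, so peaks offset from each other were not tested. Over 24330 genes, 100% of planted genes with a territory under 20 kb or of 20 to 50 kb were called, and 0% of those above 200 kb; 2 other genes were called in each of the simulations with territories under 20 kb and of 20 to 50 kb. Of random lists of 40 genes, 2.5% had p under 0.05, against 79% of lists with 15 percentage points more hits. Alternatives covered the overlap rule, the number of lists, stricter scores, peak width, repeats, distance to the TSS, matching, the TSS map, and each list or technical batch left out. GATC content and the androgen response element were planned but not analysed here, because no genome sequence was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.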

Results

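AR and p300 contacts on DNA were profiled by split-DamID in the external genitalia of male mouse embryos at E17.5. Dams had received doxycycline at 100 mg/kg daily from E13.5 to E16.5 and tamoxifen at 200 mg/kg daily from E14.5 to E16.5, and 2.5 µg of genomic DNA was used per specimen. The design held 7 SpDAM+; Msx2Rtta+ samples and 5 SpDAM-; Msx2Rtta- samples, the latter being the background of the assay. The 7 deposited peak lists could not be assigned to these groups, so they were compared with each other and with chance, and no replicate error of a group could be given.

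The lists held 98630 peaks, with 20951, 16463, 25560, 10951, 9574, 6716 and 8415 peaks in lists 1 to 7. Peaks were 248 to 468 bp wide in lists 1 to 3 and 58 to 64 bp wide in lists 4 to 7, and this split was treated as a technical batch. Lists 1 to 3 named shared comparison libraries, and lists 4 to 7 named none. The median peak held 5 to 16 reads. If scores follow HOMER's default scale, which the sources do not state, the depth was 746715, 2095144, 929048, 582362, 732705, 353359 and 280845 reads in lists 1 to 7, and peaks held 12.9% to 49.0% of it.

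**Figure D1:**
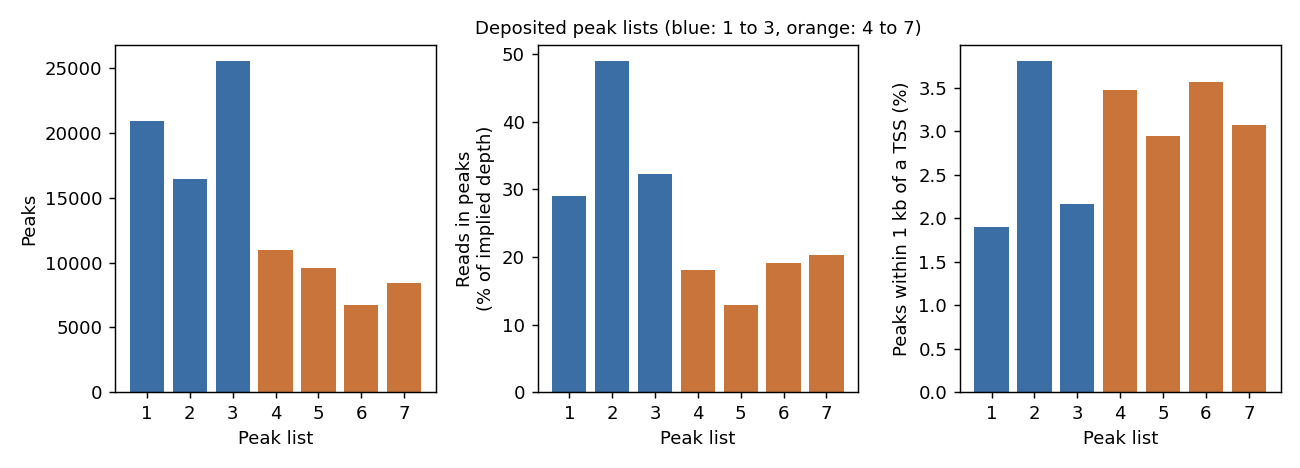
Number of peaks, percent of the implied depth in peaks and percent of peaks within 1 kb of a TSS, one bar per deposited peak list (blue, lists 1 to 3, and orange, lists 4 to 7). Lists 1 to 3 held 16463 to 25560 peaks and lists 4 to 7 held 6716 to 10951.

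Peaks lay mainly in intergenic DNA and introns, and few were at promoters. Intergenic DNA held 49.6% to 57.1% of the peaks of a list, introns 37.8% to 43.1% and promoters 1.02% to 1.89%, and repeats were annotated at 38.4% to 43.1%. Around TSSs, lists 4 to 7 had 2.96% to 3.59% of peaks within 1 kb, which was 1.49 to 1.77 times the level of peaks placed anywhere on the chromosome (two-sided permutation of positions, p = 0.0198 in each of the 4 lists, the smallest the draws can give). Against peaks moved by 20 to 200 kb, the excess in these lists was 1.23 to 1.47 times. The TSS map was built from the same deposited peaks, so ratios around TSSs may be too high, by an amount that was not measured. Lists 1 to 3 differed from each other, with ratios of 0.969, 1.90 and 1.11 against placement anywhere. Gene bodies held 41.2% to 48.4% of peaks, at most 1.18 times the level of peaks placed anywhere and 1.04 times that of moved peaks. Chromosome X held 1.86% to 3.07% of peaks, below the 3.35% that its length would give for 1 copy, and the upper 95% bound (Wilson) was below that share in 7 of 7 lists. The 3.35% takes the number of peaks as proportional to copy number, which was not tested.

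Which positions held peaks in several lists was asked next. A position assigned to Ajap1, which encodes an adherens junction protein, was in 6 of 7 lists (chromosome 4, 153664505 to 153665133, intergenic, 182 kb from the TSS) with up to 12363 reads. The second intron of Ppil1, a peptidyl-prolyl isomerase gene, held another (chromosome 17, 29257339 to 29257807, up to 193 reads). An intron position assigned to 4930552P12Rik was the remaining position in 6 lists (chromosome 19, 55551874 to 55552353). It had a SINE repeat annotation and lay 150 kb from the TSS of that gene. Positions assigned to Rtraf (chromosome 14, 19801434 to 19801902, 22.2 kb from the TSS) and Tapt1 (chromosome 5, 44402104 to 44402722, 176 kb from the TSS) were in 5 lists. The position assigned to Tapt1 had a LINE repeat annotation. Nog, which encodes a secreted BMP antagonist, was the only gene of the fixed lists to which the deposited annotation assigned a recurrent position (chromosome 11, 89207251 to 89207719). This position lay 95.1 kb from its TSS, was in lists 2, 4, 6 and 7, and held up to 1392 reads.

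In all, 33 positions were in at least 4 lists, against a mean of 0.02 and a highest count of 1 in shuffled lists (one-sided permutation of positions, p = 0.0099, the smallest the draws can give). Shuffled peaks were placed without regard to GATC sites or mappability. An excess over them therefore does not separate AR and p300 contacts from sites that the assay can detect more easily. Of these, 15 were intergenic, 13 intronic, 3 exonic and 1 at the promoter of Adh5. Both technical batches held 27 of them, as every position in at least 4 lists must unless it is in lists 4 to 7 alone. No position was in all 7 lists. At least 2 lists shared 2425 positions, against 715 by chance, and 93508 of all 95933 positions were in 1 list only. Pairs within lists 4 to 7 shared 26.3 to 39.4 times as many positions as chance, pairs within lists 1 to 3 shared 3.58 to 4.16 times as many, and pairs across the batches 1.49 to 5.59 times as many. As a share of the smaller list, these were 1.27% to 2.13% of peaks within lists 4 to 7 and 2.34% to 2.95% within lists 1 to 3, whose peaks were wider. With every peak set to 60 bp, the order turned, with 1.24% to 2.08% within lists 4 to 7 and 0.778% to 1.19% within lists 1 to 3. With a list left out and the minimum kept at 4, there were 25 positions without list 1, 12 without list 2, 19 without list 3, 13 without list 4, 20 without list 5, and 15 without list 6 or list 7. A requirement of 50% reciprocal overlap gave 6. Peaks of 58 to 64 bp cannot cover 50% of peaks of 248 to 468 bp. Only positions in all of lists 4 to 7 could therefore meet this rule, and the drop reflects peak width.

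**Figure D2:**
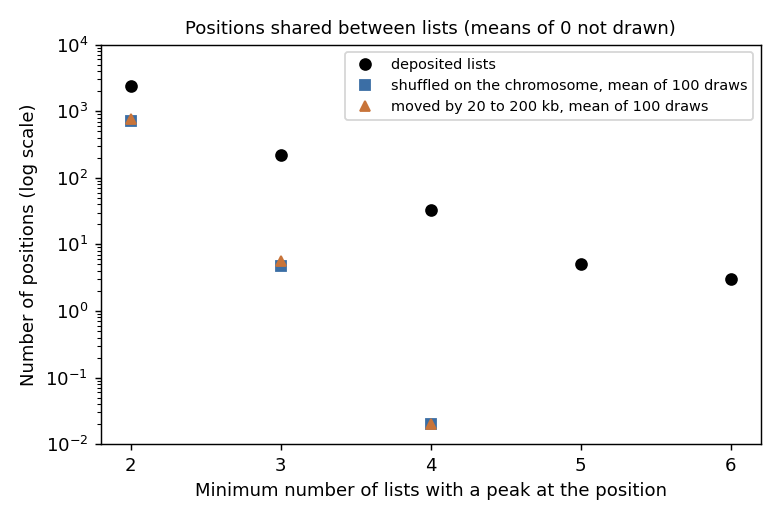
Number of positions (log scale) against the minimum number of lists with a peak there, for the deposited lists and for the means of 100 draws of both kinds of shuffle. The 33 positions in at least 4 lists stand above a chance mean of 0.02.

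Recurrent peaks were compared with peaks in no other list. Promoters were rare in both groups, with Adh5 giving the 4 promoter peaks among 146 recurrent peaks. The promoter share was higher among recurrent peaks in 4 of 7 lists, with a median difference of 2.13 percentage points, and passed Fisher's exact test in 0 of them (lowest adjusted p = 0.660). It was lower in lists 1 to 3, where no recurrent peak was at a promoter. These lists had 11, 26 and 17 recurrent peaks and single-list shares of 0.976%, 1.85% and 1.19%. So few peaks cannot show a direction. With peaks in at least 2 lists taken as recurrent, the share was higher in 7 of 7 lists and passed in 2 (lowest adjusted p = 0.0473, Fisher's exact test). Recurrent peaks such as those assigned to Ajap1 and Nog held more reads than single-list peaks in 7 of 7 lists, with medians of 6 to 188 against 5 to 15 reads and a median ratio of 1.57. The difference passed the permutation test in 5 lists, with adjusted p from 7e-05 to 0.00409, and did not in list 5 (adjusted p = 0.109) or list 7 (adjusted p = 0.557). Within lists 1 to 3 the ratios of medians were 2.63 to 12.5, and within lists 4 to 7 they were 1.20 to 1.57.

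The genes nearest to peaks in every list were then examined. Of the 18765 genes named, 832 had a peak in all 7 lists. First among them by score were Ajap1, the zinc finger genes Tshz3 and Tshz1, and Efna5, an ephrin gene. Others of the 25 leading genes were Efnb2, Gnai1, Dlk1, Sorcs3, Nedd4l, Nrxn3, Cox7c and Actr3. These genes lay in wide territories. Ajap1 was the nearest gene over 626 kb and had 51 peaks where 25.2 were expected, and Tshz3 over 983 kb had 53 where 39.8 were expected. Efna5 over 2150 kb had 66 peaks where 89.1 were expected, and Efnb2 over 1792 kb had 65 where 75.9 were expected. Dlk1 was nearest over 237 kb and had 17 peaks where 8.86 were expected. From territory alone, each of the 25 genes was expected in at least 4.42 lists, and 11 of them had no position shared by 2 lists.

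Genes in all 7 lists had a median territory of 540 kb, against 46.4 kb for all genes. Shuffled peaks gave 937 such genes on average, and peaks moved by 20 to 200 kb gave 843, against 833 with gene names assigned in the same way. With names assigned in that way, 5903 genes had peaks in at least 4 lists (5882 by the deposited names), 1.11 times the count of peaks placed anywhere (two-sided permutation of positions, p = 0.0198, the smallest the draws can give) and 1.00 times that of moved peaks (p = 0.535). The map behind these assigned names was built from the same deposited peaks, so the 1.11 times may be too high. Across genes, which are not independent replicates, the expected and observed numbers of lists had a Spearman rho of 0.758.

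**Figure D3:**
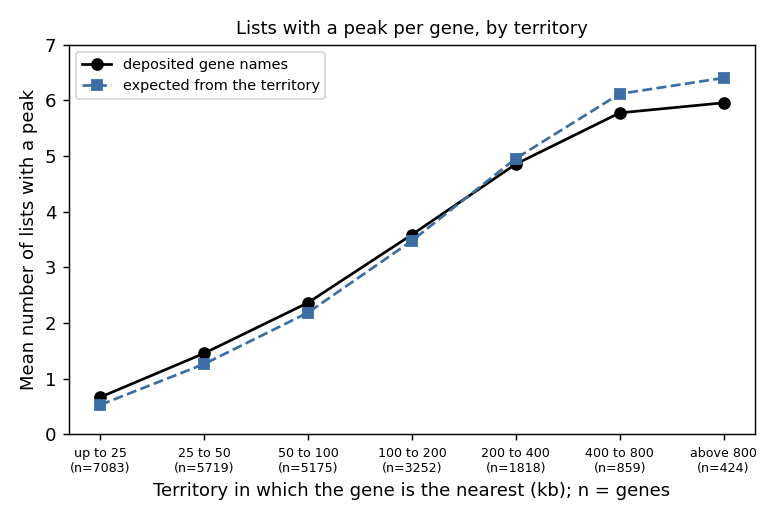
Mean number of lists with a peak per gene against the territory in which the gene is the nearest (kb), for the deposited gene names and for the expectation from territory. Observed and expected means rise together from below 1 list to 5.96 and 6.40 lists.

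Above the expectation of their territory stood 4 genes, named after their values were seen. By the exact Poisson-binomial tail, Rtraf was in 7 lists where 1.38 were expected (adjusted p = 0.0366), Ppil1 in 6 where 0.608 were expected (adjusted p = 0.0278), Mir8096 in 6 where 0.713 were expected (adjusted p = 0.0320), and Mrpl12, which encodes a mitochondrial ribosomal protein, in 6 where 0.626 were expected (adjusted p = 0.0278). These calls rested on few peaks, 6 to 8 per gene. The tail takes lists as independent, but lists shared positions above chance, and one position gave peaks to 6 lists at Ppil1, 5 at Rtraf, 4 at Mrpl12 and 3 at Mir8096, so the calls of Ppil1, Rtraf and Mrpl12 repeat recurrent positions. The recurrent positions of Rtraf and Mrpl12 lay outside these genes, in annotated introns of other transcripts, and were assigned by the nearest TSS. None of the 4 passed without list 1, 2, 5 or 7, and 1 of them passed without list 3 (Mir8096), list 4 (Mrpl12) or list 6 (Ppil1). None passed when expected peaks were scaled within bins of territory.

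Whether genes of genital development and androgen response collected peaks was asked with the fixed lists. Of 59 genital development genes, 33 had a peak in at least 4 lists where 29.4 were expected (gene permutation, adjusted p = 1). Counting only peaks within 50 kb of the TSS, 22 did where 12.6 were expected (gene permutation, adjusted p = 0.0570), and within 10 kb 0 did where 0.669 were expected. Efnb2, Sall1, Isl1 and Fgfr2, a receptor of fibroblast growth factors, each had a peak in 7 lists. Fgfr2 had 22 peaks where 11.3 were expected, and Isl1 had 28 where 34.0 were expected. Of 40 androgen targets, 19 had such peaks where 16.3 were expected (gene permutation, adjusted p = 1), with Ank3, Maf, Igf1r and Inpp4b in 7 lists. Igf1r, the receptor of insulin-like growth factor, had 16 peaks where 9.33 were expected and up to 1034 reads at one of them, Inpp4b had 18 where 29.4 were expected, Maf 47 where 43.7 were, and Ank3 26 where 22.6 were.

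Signalling genes were close to the matched expectation. The counts were 9 of 21 hedgehog genes (9.42 expected), 22 of 55 WNT genes (22.4 expected), 16 of 39 FGF genes (15.6 expected) and 22 of 49 BMP and TGF-beta genes (21.2 expected), each with adjusted p = 1 by gene permutation. Gli2 and Gli3, transcription factors of hedgehog signalling, had peaks in 7 lists where 4.72 and 6.42 were expected. Shh and Hhip had peaks in 6 where 5.88 and 6.03 were expected. Among WNT genes, Axin2, Ror1, Tcf7l2 and Fzd8 had peaks in 7 lists where 5.18, 5.24, 5.85 and 6.62 were expected. Axin2 had 16 peaks where 10.6 were expected. Fgf12, Fgf9 and Kl had peaks in 7 lists where 6.43, 6.27 and 5.20 were expected. Bmper and Acvr2a had peaks in 7 lists where 6.82 and 6.98 were expected. Nog and Bmpr1b had peaks in 6 where 4.51 and 6.24 were expected. In that order, these genes had 36, 49, 10 and 15 peaks where 35.1, 64.2, 7.90 and 20.7 were expected.

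Cell type markers gave one list outside the range of matched genes before adjustment. Neuronal genes had 27 of 37 members in at least 4 lists where 20.9 were expected (gene permutation p = 0.0080, adjusted p = 0.120), among them Nrxn3, Rbfox1, Grin2a and Cntnap2. The neuronal call depended on the map of TSS positions, since it passed with the first map (19.0 expected, adjusted permutation p = 0.0330). There the deposited names were set against territories of the first map, and these disagree in part by construction. Epithelial genes counted 16 of 48 (12.8 expected), with Klf4, Tfap2b, Dsc3 and Grhl2 in 7 lists, and mesenchymal genes 23 of 42 (22.6 expected), with Twist2, Runx2 and Postn in 7 lists. Liver genes counted 6 of 34 (6.51 expected), blood genes 3 of 27 (3.50 expected), endothelial genes 8 of 25 (8.70 expected) and muscle genes 3 of 29 (4.83 expected). Housekeeping genes counted 3 of 32 (2.70 expected). Nuclear receptors and coregulators counted 17 of 36 (15.0 expected), with Nr3c1, Nr3c2 and Ar in 7 lists. Each of these 7 lists and the receptor list had adjusted p = 1 by gene permutation, so 0 of the 15 lists passed, and 1 passed at an unadjusted p under 0.05. No member of any list passed on its own, adjusted over all genes or adjusted over the list alone.

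Further settings changed these calls. Without matching on territory, genital development, mesenchymal and neuronal genes passed. Without repeat-annotated peaks, genital development genes passed, with 29 in at least 4 lists where 20.2 were expected (gene permutation, adjusted p = 0.0450).

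**Figure D4:**
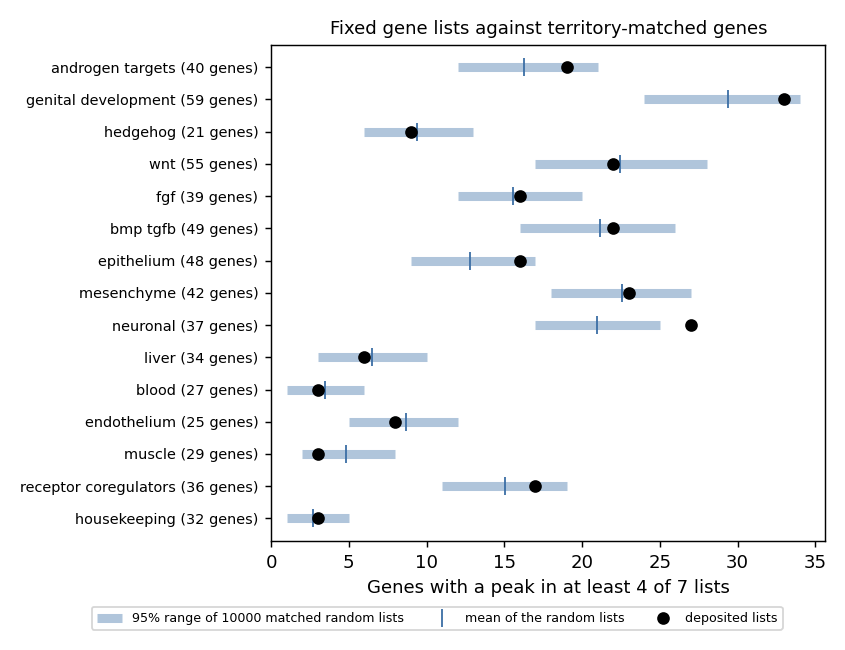
Number of genes of each fixed list with a peak in at least 4 of 7 lists (points), with the mean (tick) and 95% range (bar) of 10000 random lists matched on territory. Neuronal genes lie outside their range, at 27 against 20.9 (gene permutation, adjusted p = 0.120 over 15 lists).

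The genes behind the fusion proteins and the driver had peaks as follows. Ar had 15 peaks in 7 lists where 11.5 peaks were expected, the nearest 18.9 kb from its TSS. Ep300, which encodes p300, had 6 peaks in 4 lists where 4.16 were expected. Msx2, the source of the promoter of the driver, had 13 peaks in 5 lists where 4.81 peaks were expected, the nearest 5.61 kb away. Peak counts of single genes were not tested. From territory, Ar was expected in 5.06 lists, Ep300 in 3.00 and Msx2 in 3.30. By the Poisson-binomial tail the unadjusted p was 0.0829, 0.339 and 0.168, and none passed.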

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

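The 11 measures compared across lists, and the tests of explanations, were chosen after the lists had been seen; what would count for or against each explanation was written before its own value was computed, except for repeats, where it was written after.

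List 2 stood far from the other lists on 3 of 11 measures by Dixon's test, which chance passes in about 1 of 20 cases. Its median of 16 reads per peak compared with at most 8 in another list, its implied depth of 2095144 reads with at most 929048, and its highest peak, nearest to Gng13, took 4.51% of that depth against at most 1.51%. These measures are related, and the depth holds only under the assumed scale. No explanation was tested.

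Positions in at least 4 of the 7 lists, such as those assigned to Ajap1 and Ppil1, exceeded chance. Enrichment much broader than 5 kb around each position was argued against as the cause. Lists with every peak moved by 1 to 5 kb formed at most 2 such positions, against 33. Each peak was moved on its own, so narrower enrichment is diluted by the test and stays open. In at least 2 lists, moved peaks gave a mean of 892.5 positions (highest 955), against 715 (highest 776) for peaks placed anywhere. Some local clustering was therefore present. A limited set of equally open positions was also argued against, since it predicted 6.46 positions (95% range 2 to 12) in at least 3 of lists 4 to 7, where 64 were found. Annotated repeats were argued against as the cause of all positions, since 24 of the 33 had no repeat annotation in any list. Leaving out repeat-annotated peaks therefore had to keep at least 24. It gave 25 (at most 1 in shuffled lists, whose peaks could still land in repeats), which adds little. For the 9 positions with a repeat annotation, collapsed copies stay open. Their share of 27.3% (95% interval 15.1% to 44.2%) overlapped the 38.7% to 43.1% of single-list peaks. The placement of GATC sites, unequal mappability, fragment length and amplification were not tested. No biological explanation was tested because no list is tied to a group.

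Sharing was further above chance within lists 4 to 7 than within lists 1 to 3. As a share of the smaller list it was lower at the deposited widths (1.27% to 2.13% against 2.34% to 2.95%). With every peak set to 60 bp, the order of the shares turned, to 1.24% to 2.08% against 0.778% to 1.19%. Wider peaks in lists 1 to 3 were argued against as the whole cause: with every peak set to 60 bp, pairs within lists 1 to 3 reached 7.47 to 9.67 times chance (median 8.95), and pairs within lists 4 to 7 stayed at 25.6 to 42.6 times. The greater length of lists 1 to 3, with the weaker peaks that it adds, is a candidate explanation. With the 6716 top-scoring peaks of each list, all 60 bp, pairs within lists 1 to 3 reached 23.4 to 34.2 times chance (median 33.0). Pairs within lists 4 to 7 stood at 35.0 to 44.2 (median 41.2). This test equalises length and width together and keeps only the highest-scoring peaks of longer lists, while list 6 keeps all of its peaks. Length therefore cannot be told apart from peak score. Other differences in peak calling and the comparison libraries shared by lists 1 to 3 were not tested.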

How the results depend on the processing

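Chosen after the data were seen were the settings with all peaks at 60 bp, by technical batch, with other numbers of lists for promoter share and reads, moved peaks and repeats for TSS and gene counts, both TSS maps, and all settings for genes above their territory. The number of recurrent positions (33) was above chance under every setting except all 7 lists (0 positions, permutation p = 1); whether the same positions were kept was not followed. There were 218 in at least 3 lists, 5 in at least 5, 6 with 50% reciprocal overlap, 13 in the upper part by score, 21 with equal numbers of top peaks, 15 at 60 bp and 64 within lists 4 to 7 (at least 3 of 4), and 12 to 25 with a list left out (12 without list 2, 13 without 4, 15 without 6 or 7, 19 without 3, 20 without 5). Stricter rules and fewer lists or peaks lower such counts by construction. Under 50% reciprocal overlap, peaks of lists 1 to 3 and of lists 4 to 7 cannot match because of their widths. The promoter difference was -1.19 percentage points in lists 1 to 3, where no recurrent peak was at a promoter. With 11 to 26 recurrent peaks per list, this shows no direction. The promoter share was higher in 7 of 7 lists within 5 kb of a TSS (0 passing). With at least 2 lists it was higher in 7 of 7 (2 passing, lowest adjusted Fisher's exact p = 0.0473). For the upper against the lower scores it was higher in 6 of 7 (2 passing, lowest adjusted Fisher's exact p = 0.000247). More reads in recurrent peaks held in direction throughout, but within lists 4 to 7 (ratio 1.41) 2 of 4 lists passed; the cause was not tested. The median excess of peaks within 1 kb of a TSS kept its direction in all 3 alternatives, from 1.25 to 2.41 times; the highest is without repeat peaks, where shuffled peaks can still land in repeats, so that value and the 1.13 times for genes in at least 4 lists are inflated. Genes in at least 4 lists came to 1.00 times chance with moved peaks. These TSS and gene ratios used TSS maps built from the deposited peaks, which may raise them.

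Gene lists passed in 3 of 16 alternatives: 3 lists passed without matching and 1 without repeat peaks (genital development). The remaining alternative was the first TSS map set against the deposited names, where neuronal genes passed (adjusted permutation p = 0.0330). The lowest adjusted p ranged from 1.35e-06 to 1 over alternatives, and 0 lists passed with any list left out. Genital development genes within 50 kb of the TSS counted 22 where 12.6 were expected (adjusted permutation p = 0.0570). The TSS map was replaced after the neuronal call had been seen. Genes above their territory were 4 with both maps when names were assigned by the map, and 70 when the first map was set against the deposited names, where names and territories disagree by construction. They were 9 without repeat peaks (all 4 among them), 0 in lists 4 to 7, 0 with scaled expectations, and 0 to 1 with a list left out (0 without list 2, 5 or 7, 1 without list 3, 4 or 6, and 1 without list 1, Msx3, which is not among the 4); the cause was not tested. No paired analysis was possible because no list is tied to a sample, so replicate numbers could not be used. GATC content, the androgen response element and the contrast of SpDAM+ with SpDAM- were not run. A median of 5 to 16 reads per peak limits what a missing peak in a list shows.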

Other observations

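The tests of chromosome X and of repeats around genital development genes were chosen after these patterns had been seen, with predictions written before their own values.

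Of 92 positions with at least 1000 reads, 56 were in 1 list only, against 93508 of all 95933 positions. List 2, which had the greatest implied depth, held at least 1000 reads at 78 of the 92, so the cut does not treat the lists alike. The highest lay nearest to Gng13, which encodes a G protein subunit, with 94444 reads in list 2 and peaks in lists 1 to 3 (chromosome 17, 25699810 to 25700298). Intron 1 of Col26a1, a collagen gene, held up to 5708 reads in 3 lists, and a position nearest to Fgf9 held up to 2146 reads in 3 lists. A further recurrent position lay nearest to Msx1os, the antisense partner of the homeobox gene Msx1 (chromosome 5, 37815827 to 37816295, 4 lists). Positions shared with another list held 5.28% to 24.1% of the peak reads of a list, from 4.37% to 7.22% of its peaks.

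Chromosome X held fewer peaks than its length gives for 1 copy. A candidate explanation is fewer peaks on gene-poor chromosomes. Predicted from gene density over 19 autosomes and halved for 1 copy, the X density lay inside the 95% interval in 3 lists and below it in 4. It was below the predicted value itself in every list. The relation over autosomes had a Spearman rho from 0.091 to 0.795, and was nearly absent in list 1, which counted as inside. Gene density therefore cannot be told apart from other causes. The length share and the halved prediction both take the number of peaks as proportional to copy number, which was not tested.

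Genital development genes passed against matched genes only where repeat-annotated peaks were left out. A candidate explanation is that fewer of their peaks carry repeats: the share was 35.9%, against a mean of 42.5% (36.0% to 49.0%) for matched genes. This is marginal, with a gene permutation p = 0.0470 unadjusted and adjusted p = 0.154 over 15 lists. Androgen targets (31.8%), WNT genes (33.4%) and muscle genes (24.4%) also had unadjusted p under 0.05 and did not pass without repeat peaks, so the share of repeats alone does not separate the list that passed.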
